A study of Homo sapiens with 12 samples.

How the data were processed

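RNA of HUVEC was sequenced with a stranded kit in 12 libraries of 4 groups. Per the labels, a replicate number is a batch number, with 3 batches in every group, and cells were kept in EGM-2 medium. Per the submitters' processing notes, Salmon and DESeq2 were used with the genome GRCh38.p14, and the versions are not given in the sources used here. Per the file headers, each library's file listed transcripts with the expected or estimated count of reads, TPM, and other columns such as the effective transcript length. The deposited estimated counts were used for the tests, and the deposited effective lengths for 1 alternative. The deposited TPM values weighted the transcripts of each gene when effective lengths were averaged for that alternative.

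Each file held 177456 transcripts, and 167027 of them (94.1%) matched GENCODE release 29, while 10429 did not and were left out. Estimated counts were summed over the transcripts of each gene and rounded, giving 35052 genes, of which 34878 had a symbol in a table of gene names. Positions are those of GRCh38 in that annotation. Reads of genes with near-identical copies, of HLA genes and of overlapping genes were shared out by Salmon's model and are uncertain. Matched genes held 33491700 to 45272700 reads per library. No library was a copy of another.

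Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 14210. Counts were scaled by TMM and fitted with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) by quasi-likelihood over all 12 libraries with a mean per group. The common biological coefficient of variation was 12.0%. The 4 pairs of groups and the interaction were tested, with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. Whether batches are separate donors or cultures is not given in the sources used here, and their spread may be technical. CPM values are counts divided by scaled library size, and log2 CPM used a prior count of 2. The value after ± is a standard error from the fit for a log2 fold change or log2 interaction, and an SD for CPM. Gene lists fixed before the data were examined were tested with camera (preset correlation 0.01, and again with an estimated correlation) on 37 lists. A list of erythroid markers had 0 tested genes. List medians are log2 fold changes, and counts with p adjusted over the list alone are given only where they differ. The choice of tests, lists, named genes and alternatives was made before the data were examined, except where stated.

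The genes named were, for each comparison, the 8 largest changes each way (5 for flow with A-485 and for A-485 in static culture) among called genes with a mean log2 CPM of at least 2, the same sign in all 3 batches and a symbol that is not that of a clone, antisense, pseudogene, small RNA or readthrough transcript, up to 4 members of each list with the smallest p, and 10 genes set in advance (EP300, CREBBP, KLF2, KLF4, NOS3, THBD, CYP1B1, EDN1, ANGPT2 and VCAM1). Genes on the sex chromosome Y, XIST and TSIX were left out. Of the genes chosen by this rule, 1 is not reported here. A batch with no reads in either library gave no sign, a rule settled after the data were seen, by which BTBD7 was dropped and CORO7 was kept only for A-485 under flow. A group in which every library had 3 reads or fewer was at the floor, and no fitted fold is given against it. With no reads, a fold is a lower bound against 3 reads per library, and with some reads the ratio has an exact 95% interval for counting error only.

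The batch numbers of the labels pair the samples. After group means were removed, libraries of different groups correlated at -0.03 to 0.17 with the same number (above 0.1 in 6 of 18 pairs) and at -0.19 to 0.13 with another (1 of 36), and 10 of 12 libraries correlated best with their own number. The fit chosen before the data were examined had no batch term, and batch was tried as a block. The other alternatives were DESeq2 1.42.0, median-of-ratios scaling, no filter, a stricter filter (1 CPM in 3 libraries), an offset for transcript length, the compared groups alone, and each library left out in turn. Library size scaling was added after the data were seen. The fit was tested on simulated counts of 14006 genes with known changes. For flow with vehicle it called 97.1% of genes lowered 2-fold and 87.9% of those raised 2-fold, 97.1% and 100% of those lowered and raised 4-fold, and 54.5% and 66.7% of those changed 1.5-fold. It called 0.0435% of unchanged genes there and 0.0653% in the interaction, where 60% of 30 genes lowered 2-fold only under flow with A-485 were called. For flow with vehicle, 13806 of the 14006 simulated genes were unchanged, the changed ones had a mean above 1 CPM, and no batch differences were simulated. In the data 42.5% of genes were called in that comparison, so these rates may not hold for the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.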

Results

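RNA was sequenced from HUVEC, primary cells taken from the vein of the umbilical cord. The 12 libraries formed 4 groups of 3, labelled as batches 1 to 3. Cells were kept in static culture or under fluid shear stress of 15 dyn/cm2 for 24 h, each with DMSO vehicle or with 5 µM A-485. A-485 blocks the acetyltransferase activity of the coactivators p300 and CBP, which acetylate histones at enhancers. Each library held 34280000 to 46302400 estimated reads, and 97.6% to 97.9% of them fell on transcripts that matched an annotated gene. After a filter on low counts, 14210 genes were tested. The first principal component (60.5% of variance) parted the A-485 libraries from the vehicle libraries, and the second (19.7%) parted flow from static culture. p-values measure the spread between samples labelled as separate batches.

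**Figure D1:**
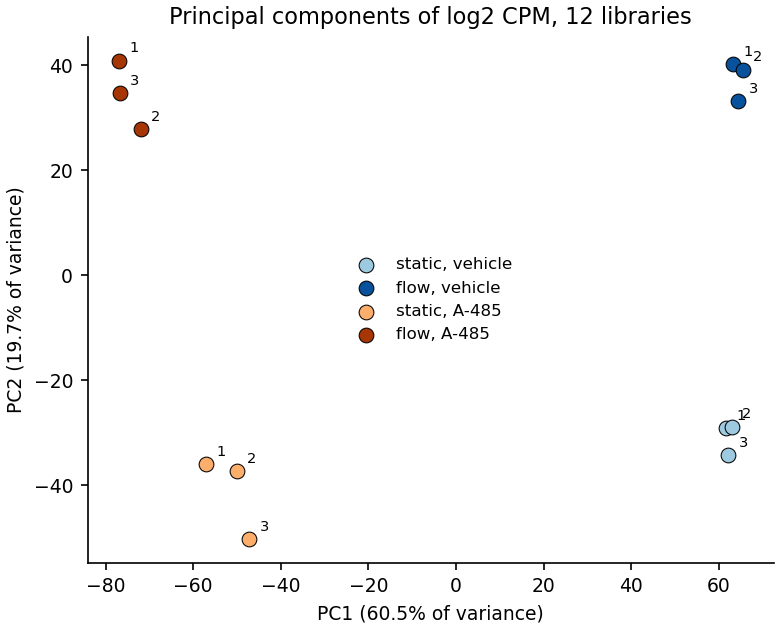
Each point is 1 library placed by principal components of log2 CPM, with the percent of variance on each axis, the group as colour and the batch number beside it. The first component (60.5%) separates A-485 from vehicle and the second (19.7%) separates flow from static culture.

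Flow with vehicle was compared with static culture to give the response to shear stress without the inhibitor. Flow raised the transcription factors KLF2 and KLF4, which carry much of the anti-inflammatory response of endothelium to laminar flow, together with 17 of 25 NRF2 targets and all 6 aryl hydrocarbon receptor targets. It lowered 16 of 23 NF-kB inflammatory and adhesion genes and 14 of 31 interferon-stimulated genes. Camera called these 4 lists, and none kept its call with an estimated correlation (adjusted p = 0.0682 to 0.478). The list of mitosis genes had no camera call. KLF2 (GRCh38 chromosome 19, 16324817 to 16327874) rose from 33.3 ± 7.45 to 161 ± 14.7 CPM (SD, n = 3 per group). Its log2 fold change was 2.28 ± 0.23 (SE, as after every log2 fold change and log2 interaction below). The adjusted p was 2.09e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with the same sign in 3 of 3 batches. KLF4 (chromosome 9, 107484852 to 107490482) also rose (log2 fold change 3.00 ± 0.20, adjusted p = 1.04e-06, 3 of 3 batches), as did NOS3 (chromosome 7, 150990995 to 151014588), the endothelial nitric oxide synthase (log2 fold change 0.97 ± 0.14, adjusted p = 0.000232, 3 of 3). THBD (chromosome 20, 23045633 to 23049741), the anticoagulant receptor thrombomodulin, did not pass (log2 fold change 0.67 ± 0.34, adjusted p = 0.125), nor did EDN1 (chromosome 6, 12290363 to 12297194), the vasoconstrictor endothelin (log2 fold change -0.27 ± 0.25, adjusted p = 0.426). ANGPT2 (chromosome 8, 6499651 to 6563409), which destabilises vessels, fell from 253 ± 98.5 to 55.6 ± 14.2 CPM (log2 fold change -2.19 ± 0.33, adjusted p = 0.000263, 3 of 3). VCAM1 (chromosome 1, 100719742 to 100739045), a leukocyte adhesion molecule, was near the floor under flow and 49.9-fold lower (95% counting interval 24.0 to 125), adjusted p = 5.55e-05, with the same sign in 3 of 3 batches. Neither target of the inhibitor passed, with EP300 at log2 fold change -0.17 ± 0.13 and CREBBP at log2 fold change -0.05 ± 0.12. THBD gained a call without static A-485 replicate 3 (adjusted p = 0.0404).

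Of 22 tested shear-induced genes from earlier knowledge of endothelium, 15 rose, 4 fell and 3 did not pass. Their median was 1.29 in log2 (camera adjusted p = 8.76e-05, 0.404 with an estimated correlation). Among them were HMOX1, which degrades haem (log2 fold change 2.60 ± 0.20), and NQO1, a quinone reductase (log2 fold change 1.46 ± 0.10). Among 6 tested targets of the aryl hydrocarbon receptor (a xenobiotic sensor), 6 rose, 0 fell and 0 did not pass. Their median was 2.23 in log2 (camera adjusted p = 2.22e-05, 0.0682 with an estimated correlation). TIPARP and AHRR, which restrain that receptor, rose (log2 fold change 1.71 ± 0.07 and 0.97 ± 0.11). CYP1B1 (chromosome 2, 38066973 to 38109902), a xenobiotic oxidase, had 0 to 3 reads in each static vehicle library and was 83.5-fold higher under flow (counting interval 32.3 to 309), adjusted p = 7e-05, same sign in 3 of 3 batches. Of 25 tested antioxidant targets of NRF2, 17 rose, 0 fell and 8 did not pass. Their median was 0.54 in log2 (camera adjusted p = 2.22e-05, 0.404 with an estimated correlation). TALDO1, of the pentose phosphate pathway, rose (log2 fold change 0.78 ± 0.08), as did the exporter ABCC3 (log2 fold change 2.00 ± 0.23). Among 24 tested genes of TGF-beta signalling and mesenchymal transition, 11 rose, 2 fell and 11 did not pass. Their median was 0.44 in log2 (camera adjusted p = 0.00802, 0.468 with an estimated correlation). TGFBI, a matrix protein, rose (log2 fold change 3.50 ± 0.26), as did TAGLN, an actin-binding protein (log2 fold change 2.61 ± 0.23). Of 19 tested coagulation and fibrinolysis genes, 10 rose, 3 fell and 6 did not pass (adjusted over the list alone, 12 rose and 3 fell). Their median was 0.67 in log2 (camera adjusted p = 0.00619, 0.404 with an estimated correlation). The protease receptor F2RL1 rose (log2 fold change 1.67 ± 0.11).

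Among 23 tested NF-kB inflammatory and adhesion genes, 0 rose, 16 fell and 7 did not pass (adjusted over the list alone, 0 rose and 18 fell). Their median was -1.46 in log2 (camera adjusted p = 3.09e-06, 0.478 with an estimated correlation). CCL2, a monocyte attractant, fell (log2 fold change -2.11 ± 0.19), as did RELB, an NF-kB subunit (log2 fold change -1.54 ± 0.17). Of 31 tested interferon-stimulated genes, 1 rose, 14 fell and 16 did not pass. Their median was -0.49 in log2, or -0.45 with genes at the floor held there (camera adjusted p = 0.00118, 0.478 with an estimated correlation). The antiviral genes MX1 (log2 fold change -2.03 ± 0.21) and IFIH1 (log2 fold change -1.48 ± 0.18) fell. Among 14 tested genes of MHC class I antigen presentation, 0 rose, 5 fell and 9 did not pass. Their median was -0.41 in log2 (camera adjusted p = 0.0137, 0.478 with an estimated correlation). B2M, the shared light chain, fell (log2 fold change -0.49 ± 0.10), and HLA-B also fell but shares reads with other HLA genes and is uncertain. Of 20 tested shear-repressed genes, 4 rose, 9 fell and 7 did not pass. Their median was -0.27 in log2 (camera adjusted p = 0.138). BMP4, a growth factor made under disturbed flow, fell (log2 fold change -1.76 ± 0.10). Among 21 tested genes of the Notch pathway and arterial identity, 5 rose, 9 fell and 7 did not pass. Their median was -0.51 in log2 (camera adjusted p = 0.0539). Within it LFNG, which modifies Notch, rose (log2 fold change 2.94 ± 0.18) and SEMA3G fell (log2 fold change -2.33 ± 0.14). Of 30 tested genes of mitosis, 0 rose, 0 fell and 30 did not pass. Their median was 0.17 in log2 (camera adjusted p = 0.443). The Notch pathway and arterial genes list gained a call without flow vehicle replicate 2 or flow vehicle replicate 3 or with no filter or with the transcript length offset (adjusted p = 0.0249 to 0.0431). The mitosis list gained a call with only the compared groups fitted (adjusted p = 0.0224).

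Smaller shifts with a camera call were seen in genes of DNA replication (17 rose and 0 fell of 30, median 0.25, moving to 0.16 with library size scaling, camera adjusted p = 0.00141, 0.566 with an estimated correlation), MYC and ribosome biogenesis genes (12 rose and 0 fell of 26, median 0.36, camera adjusted p = 0.00504, 0.607 with an estimated correlation) and oxidative phosphorylation genes (10 rose and 0 fell of 30, 9 and 0 adjusted over the list alone, median 0.18, moving to 0.09 with library size scaling and 0.12 without flow vehicle replicate 2, camera adjusted p = 0.00141, 0.607 with an estimated correlation). The same held for glycolysis and hypoxia genes (15 rose and 4 fell of 27, median 0.26, moving to 0.17 with library size scaling, camera adjusted p = 0.0405, 0.607 with an estimated correlation), SRF and actin genes (7 rose and 1 fell of 23, median 0.18, moving to 0.09 with library size scaling and 0.09 to 0.09 without flow vehicle replicate 1 or static vehicle replicate 2, camera adjusted p = 0.039, 0.607 with an estimated correlation) and ribosomal protein genes (4 rose and 0 fell of 30, 0 and 0 adjusted over the list alone, median 0.16, moving to 0.07 with library size scaling and 0.06 to 0.25 without flow vehicle replicate 1 or flow vehicle replicate 2, camera adjusted p = 0.042, 0.759 with an estimated correlation), the last with an adjusted p = 0.0651 with the replicate block. Lower shifts were seen in cholesterol synthesis genes (1 rose and 9 fell of 26, median -0.21, camera adjusted p = 0.0339, 0.604 with an estimated correlation) and acetyltransferase, deacetylase and bromodomain genes (3 rose and 12 fell of 30, 3 and 15 adjusted over the list alone, median -0.24, camera adjusted p = 0.0265, 0.485 with an estimated correlation). Camera called 16 of 37 lists, and 0 with an estimated correlation. The glycolysis and hypoxia list lost its call without flow vehicle replicate 2 or static vehicle replicate 2 or with the transcript length offset (adjusted p = 0.0531 to 0.069). The SRF and actin cytoskeleton genes list lost its call without flow vehicle replicate 1 or static vehicle replicate 2 or with the stricter filter (adjusted p = 0.0528 to 0.192). The ribosomal proteins list lost its call without flow A-485 replicate 2, flow vehicle replicate 2, static A-485 replicate 1, static A-485 replicate 2, static A-485 replicate 3, static vehicle replicate 1 or static vehicle replicate 2 or with the stricter filter, with the replicate block, with only the compared groups fitted or with library size scaling (adjusted p = 0.0524 to 0.466). The cholesterol synthesis list lost its call without flow vehicle replicate 3 or static vehicle replicate 1 (adjusted p = 0.0565 to 0.0806). The acetyltransferases, deacetylases and bromodomain proteins list lost its call without flow vehicle replicate 2 or static vehicle replicate 2 (adjusted p = 0.0531 to 0.0639).

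Among single genes with the largest changes, PI16, a peptidase inhibitor (log2 fold change 7.11 ± 0.56), and ANGPTL4, a lipase inhibitor (log2 fold change 5.60 ± 0.32), rose. IL33, an alarmin (log2 fold change -6.68 ± 0.32), the gap junction gene GJA4 (-5.04 ± 0.40), the chemokine CXCL8 (-4.91 ± 0.77) and the netrin receptor UNC5B (-4.45 ± 0.30) fell. INHBB, an activin subunit, was 214-fold lower under flow (counting interval 108 to 495). Of 14210 genes, 3087 rose and 2951 fell, and 336 and 805 of these changed at least 2-fold. Of the called genes, 99.6% had the same sign in all 3 batches. With library size scaling 35.9% of calls were higher, against 51.1% with TMM, and the median of all genes moved to -0.08 in log2.

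Flow with A-485 was compared with static culture with A-485 to give the response to shear stress while p300 and CBP were inhibited. KLF2, KLF4 and 17 of 25 NRF2 targets rose here as well. Of the mitosis genes 29 of 30 fell, and of the interferon-stimulated genes 20 of 31. Camera called these 3 lists, and none kept its call with an estimated correlation (adjusted p = 0.58 for each). Targets of the aryl hydrocarbon receptor went both ways. KLF2 rose from 89.8 ± 30.9 to 471 ± 17.9 CPM (SD, n = 3 per group; log2 fold change 2.39 ± 0.23, adjusted p = 7.46e-06 in edgeR, same sign in 3 of 3 batches) and KLF4 also rose (log2 fold change 3.47 ± 0.20, adjusted p = 2.75e-07, 3 of 3). NOS3 did not pass (log2 fold change 0.25 ± 0.14, adjusted p = 0.156). THBD rose (log2 fold change 2.62 ± 0.35, adjusted p = 7.83e-05, 3 of 3), and ANGPT2 did not pass (log2 fold change 0.47 ± 0.31, adjusted p = 0.221). EDN1 (log2 fold change -0.13 ± 0.28), EP300 (log2 fold change -0.16 ± 0.13) and CREBBP (log2 fold change -0.29 ± 0.12) did not pass. VCAM1 fell (log2 fold change -4.61 ± 0.71, adjusted p = 0.000176, 3 of 3), and CYP1B1 did not pass (log2 fold change -0.31 ± 0.68, adjusted p = 0.718). NOS3 gained a call without flow A-485 replicate 1 (adjusted p = 0.0366). CREBBP gained a call without flow A-485 replicate 2, flow A-485 replicate 3, flow vehicle replicate 2 or static A-485 replicate 1 or in DESeq2, with median-of-ratios scaling, with no filter, with the stricter filter, with the transcript length offset, with only the compared groups fitted or with library size scaling (adjusted p = 0.00607 to 0.048).

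Among 22 tested shear-induced genes, 9 rose, 3 fell and 10 did not pass (adjusted over the list alone, 9 rose and 4 fell). Their median was 0.24 in log2, or 0.20 with genes at the floor held there, moving to 0.61 with only the compared groups fitted, 0.07 with library size scaling and 0.15 to 0.68 without flow A-485 replicate 1, flow A-485 replicate 3, static A-485 replicate 1 or static A-485 replicate 3 (camera adjusted p = 0.0384, 0.58 with an estimated correlation). HMOX1 rose (log2 fold change 3.32 ± 0.20), as did the semaphorin SEMA7A (log2 fold change 3.87 ± 0.35). Of 25 tested NRF2 targets, 17 rose, 2 fell and 6 did not pass. Their median was 0.56 in log2 (camera adjusted p = 4.91e-05, 0.58 with an estimated correlation). PRDX1, a peroxidase, rose (log2 fold change 1.82 ± 0.11). Among 6 tested aryl hydrocarbon receptor targets, 2 rose, 2 fell and 2 did not pass. Their median was -0.15 in log2, while camera's direction was the other one (camera adjusted p = 0.876). TIPARP rose (log2 fold change 0.37 ± 0.07) while ALDH3A1, an aldehyde dehydrogenase, fell (log2 fold change -1.97 ± 0.43). Of 30 tested genes of mitosis, 0 rose, 29 fell and 1 did not pass (adjusted over the list alone, 0 rose and 30 fell). Their median was -1.61 in log2 (camera adjusted p = 3.43e-08, 0.58 with an estimated correlation). The kinases CDK1 (log2 fold change -1.59 ± 0.19) and TTK (-2.36 ± 0.31), which drive and check mitosis, fell. Among 30 tested genes of DNA replication, 2 rose, 18 fell and 10 did not pass (adjusted over the list alone, 2 rose and 19 fell). Their median was -0.40 in log2 (camera adjusted p = 0.00114, 0.58 with an estimated correlation). CDT1, which loads the helicase onto DNA, fell (log2 fold change -2.25 ± 0.19). Of 31 tested interferon-stimulated genes, 1 rose, 20 fell and 10 did not pass (adjusted over the list alone, 3 rose and 22 fell). Their median was -1.13 in log2 (camera adjusted p = 5.16e-06, 0.58 with an estimated correlation). IFI44L (log2 fold change -4.47 ± 0.30) and MX1 (log2 fold change -2.93 ± 0.20) fell. Among 23 tested NF-kB genes, 0 rose, 14 fell and 9 did not pass. Their median was -0.81 in log2 (camera adjusted p = 0.0076, 0.612 with an estimated correlation). The leukocyte ligand ICAM1 fell (log2 fold change -1.84 ± 0.28). The shear-induced genes list lost its call without flow A-485 replicate 3, flow vehicle replicate 3, static A-485 replicate 1 or static vehicle replicate 3 or with the replicate block (adjusted p = 0.0513 to 0.0664). The NF-kB inflammatory and adhesion genes list lost its call without static A-485 replicate 2 (adjusted p = 0.0512).

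Of 26 tested MYC and ribosome biogenesis genes, 24 rose, 1 fell and 1 did not pass. Their median was 0.66 in log2 (camera adjusted p = 1.74e-05, 0.58 with an estimated correlation). NOP16, of ribosome assembly, rose (log2 fold change 1.60 ± 0.19). Among 28 tested immediate early genes, 12 rose, 2 fell and 14 did not pass. Their median was 0.29 in log2, moving to 0.13 with library size scaling and 0.11 to 0.59 without static A-485 replicate 1, static A-485 replicate 2 or static A-485 replicate 3 (camera adjusted p = 0.0316, 0.621 with an estimated correlation). JUN, a growth-response transcription factor, rose (log2 fold change 2.38 ± 0.17). Of 19 tested coagulation and fibrinolysis genes, 11 rose, 4 fell and 4 did not pass (adjusted over the list alone, 12 rose and 5 fell). Their median was 0.86 in log2, moving to 0.51 without static A-485 replicate 3 (camera adjusted p = 0.0384, 0.58 with an estimated correlation). PLAU, the plasminogen activator urokinase, rose (log2 fold change 1.87 ± 0.10). Camera also called glycolysis and hypoxia genes (20 rose and 2 fell of 27, median 0.45, moving to 0.29 with library size scaling, camera adjusted p = 0.000474, 0.58 with an estimated correlation), oxidative phosphorylation genes (21 rose and 0 fell of 30, 23 and 0 adjusted over the list alone, median 0.28, moving to 0.11 with library size scaling, camera adjusted p = 0.000101, 0.58 with an estimated correlation) and SRF and actin genes (14 rose and 2 fell of 23, median 0.44, moving to 0.28 with library size scaling, camera adjusted p = 0.00434, 0.58 with an estimated correlation) higher. It called cholesterol synthesis genes (3 rose and 13 fell of 26, median -0.26, moving to -0.43 with library size scaling, camera adjusted p = 0.00793, 0.58 with an estimated correlation) and fibroblast markers (0 rose and 5 fell of 9, median -0.93, moving to -1.46 with only the compared groups fitted, camera adjusted p = 0.0384, 0.58 with an estimated correlation) lower. It called 14 of 37 lists, and 0 with an estimated correlation. The immediate early genes list lost its call without static A-485 replicate 3 (adjusted p = 0.168). The coagulation and fibrinolysis list lost its call with the replicate block or with only the compared groups fitted (adjusted p = 0.0636 to 0.0681). The fibroblast markers list lost its call without flow A-485 replicate 1, flow A-485 replicate 3, static A-485 replicate 2, static A-485 replicate 3 or static vehicle replicate 3 or with median-of-ratios scaling, with the replicate block, with the transcript length offset or with library size scaling (adjusted p = 0.0512 to 0.144).

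Single genes with large rises included ANGPTL4 (log2 fold change 6.50 ± 0.29), the tubulin TUBB3 (5.15 ± 0.22), the hormone STC1 (5.01 ± 1.06) and the cytokine IL11 (4.97 ± 0.65). KIT, a stem cell factor receptor, had no reads under flow with A-485 and was at least 6.06-fold lower. The retinoid enzyme DHRS3 (log2 fold change -6.44 ± 0.58) and the interferon-induced GTPase GBP4 (log2 fold change -5.49 ± 0.37) fell. Of 14210 genes, 3976 rose and 3616 fell, 457 and 1192 of them at least 2-fold, and 99.1% of calls had the same sign in all 3 batches. Library size scaling gave 32.0% of calls higher, against 52.4%, and moved the median of all genes to -0.17.

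A-485 was compared with vehicle in static culture to give the response to the inhibitor without shear stress. Most endothelial identity genes fell, among them the junction protein PECAM1, as did most arterial and venous markers. Most genes of DNA replication, mitosis, cholesterol synthesis and ribosomal proteins fell, and 24 of 31 interferon-stimulated genes rose. Camera called all of these lists, and with an estimated correlation only the arterial and venous lists kept their calls (the others had adjusted p = 0.0733 to 0.418). The median of ribosomal protein genes, -0.55, was -0.0574 after a trend in GC content, transcript length and expression was removed. Both targets of the inhibitor rose, EP300 (chromosome 22, 41091786 to 41180079; log2 fold change 0.61 ± 0.13, adjusted p = 0.00151 in edgeR, same sign in 3 of 3 batches) and CREBBP (chromosome 16, 3725054 to 3880726; log2 fold change 0.61 ± 0.12, adjusted p = 0.000704, 3 of 3). KLF2 rose (log2 fold change 1.43 ± 0.23, adjusted p = 0.000141, 3 of 3) and KLF4 did not pass (log2 fold change -0.34 ± 0.21, adjusted p = 0.174). NOS3 fell (log2 fold change -0.85 ± 0.14, adjusted p = 0.00022, 3 of 3), and THBD did not pass (log2 fold change -0.01 ± 0.34, adjusted p = 0.98). EDN1 fell from 251 ± 40.2 to 14.2 ± 7.03 CPM (SD, n = 3 per group; log2 fold change -4.14 ± 0.29, adjusted p = 1.78e-07, 3 of 3). ANGPT2 (log2 fold change -1.46 ± 0.32, adjusted p = 0.0016, 3 of 3) and VCAM1 (log2 fold change -1.50 ± 0.45, adjusted p = 0.0112, 3 of 3) fell. CYP1B1 was 7.52-fold higher (counting interval 2.67 to 29.3), adjusted p = 0.0179. VCAM1 lost its call without static vehicle replicate 2 (adjusted p = 0.104). CYP1B1 lost its call without static A-485 replicate 1, static A-485 replicate 2, static vehicle replicate 2 or static vehicle replicate 3 or with the transcript length offset (adjusted p = 0.051 to 0.0864). KLF4 gained a call without static A-485 replicate 2 (adjusted p = 0.00955).

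Among 34 tested endothelial identity genes, 1 rose, 32 fell and 1 did not pass. Their median was -1.76 in log2 (camera adjusted p = 9.98e-12, 0.0733 with an estimated correlation). PECAM1, of the cell junction, fell (log2 fold change -3.19 ± 0.16), as did LYL1, a transcription factor (log2 fold change -3.40 ± 0.17). Of 21 tested Notch and arterial genes, 0 rose, 18 fell and 3 did not pass. Their median was -2.55 in log2 (camera adjusted p = 2.41e-08, 0.0465 with an estimated correlation). The ligands JAG2 (log2 fold change -2.36 ± 0.11) and EFNB2 (log2 fold change -3.64 ± 0.17) fell. Among 8 tested venous genes, 0 rose, 8 fell and 0 did not pass. Their median was -3.01 in log2, or -2.27 with genes at the floor held there (camera adjusted p = 7.43e-05, 0.0484 with an estimated correlation). NR2F2, which sets venous identity, fell (log2 fold change -1.60 ± 0.13). Of 13 tested BMP-SMAD targets, 1 rose, 10 fell and 2 did not pass. Their median was -2.04 in log2 (camera adjusted p = 0.000126, 0.0465 with an estimated correlation). ID3, an inhibitor of differentiation, fell (log2 fold change -2.14 ± 0.08). Among 7 tested lymphatic markers, 0 rose, 5 fell and 2 did not pass. Their median was -1.45 in log2 (camera adjusted p = 0.00695, 0.075 with an estimated correlation). Of 20 tested vasoactive mediators, 1 rose, 15 fell and 4 did not pass. Their median was -1.54 in log2 (camera adjusted p = 0.000303, 0.0733 with an estimated correlation). The angiotensin-converting enzyme ACE fell (log2 fold change -3.20 ± 0.25). Among 20 tested shear-repressed genes, 0 rose, 17 fell and 3 did not pass. Their median was -2.14 in log2 (camera adjusted p = 1.8e-06, 0.0704 with an estimated correlation). Of 22 tested shear-induced genes, 4 rose, 12 fell and 6 did not pass. Their median was -1.14 in log2, or -1.01 with genes at the floor held there (camera adjusted p = 0.0207, 0.394 with an estimated correlation). The matrix regulator TIMP3 fell (log2 fold change -7.38 ± 0.49).

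Among 30 tested genes of DNA replication, 0 rose, 29 fell and 1 did not pass. Their median was -2.39 in log2 (camera adjusted p = 1.6e-13, 0.0733 with an estimated correlation). The helicase subunits MCM4 (log2 fold change -2.57 ± 0.09) and MCM5 (log2 fold change -2.55 ± 0.10) fell. Of 30 tested genes of mitosis, 0 rose, 30 fell and 0 did not pass. Their median was -1.98 in log2 (camera adjusted p = 1.17e-07, 0.418 with an estimated correlation). CDK1 fell (log2 fold change -2.46 ± 0.18). Among 26 tested cholesterol synthesis genes, 3 rose, 22 fell and 1 did not pass. Their median was -1.003 in log2 (camera adjusted p = 8.64e-07, 0.0898 with an estimated correlation). HMGCS1, an early enzyme of the pathway, fell (log2 fold change -2.21 ± 0.09). Of 26 tested MYC and ribosome biogenesis genes, 0 rose, 20 fell and 6 did not pass. Their median was -0.82 in log2, moving to -0.53 with library size scaling (camera adjusted p = 6.09e-05, 0.442 with an estimated correlation). MYC itself fell (log2 fold change -2.25 ± 0.17). Among 30 tested ribosomal protein genes, 0 rose, 30 fell and 0 did not pass. Their median was -0.55 in log2, moving to -0.26 with library size scaling (camera adjusted p = 2.46e-07, 0.418 with an estimated correlation). Of 31 tested interferon-stimulated genes, 24 rose, 1 fell and 6 did not pass. Their median was 0.76 in log2 (camera adjusted p = 2.34e-06, 0.152 with an estimated correlation). RIGI, a sensor of viral RNA, rose (log2 fold change 0.82 ± 0.08), as did the ligase HERC6 (log2 fold change 1.46 ± 0.12). Among 23 tested NF-kB genes, 5 rose, 10 fell and 8 did not pass. Their median was -0.28 in log2, and 0.01 with library size scaling (camera adjusted p = 0.674). ICAM1 rose (log2 fold change 3.37 ± 0.30) and CCL2 fell (log2 fold change -7.79 ± 0.29). No camera call was made for aryl hydrocarbon receptor targets (4 rose and 2 fell of 6, median 0.82, the mean, -0.52, had the other sign, camera adjusted p = 0.621).

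Lower shifts with a camera call were also seen in matrix genes (6 rose and 23 fell of 34, median -1.09, camera adjusted p = 0.00018, 0.176 with an estimated correlation), TGF-beta genes (3 rose and 16 fell of 24, median -0.93, camera adjusted p = 0.00759, 0.204 with an estimated correlation) and YAP/TAZ targets (1 rose and 12 fell of 21, median -0.76, moving to -0.46 with library size scaling, camera adjusted p = 0.00695, 0.211 with an estimated correlation). The same held for NRF2 targets (2 rose and 17 fell of 25, 2 and 18 adjusted over the list alone, median -0.66, moving to -0.37 with library size scaling, camera adjusted p = 0.000554, 0.176 with an estimated correlation), SRF and actin genes (2 rose and 15 fell of 23, median -0.50, moving to -0.21 with library size scaling, camera adjusted p = 0.0025, 0.418 with an estimated correlation) and stress response genes (1 rose and 16 fell of 24, 2 and 16 adjusted over the list alone, median -0.78, moving to -0.48 with library size scaling, camera adjusted p = 0.000636, 0.211 with an estimated correlation). It held for coagulation genes (2 rose and 9 fell of 19, median -0.69, moving to -0.41 with library size scaling, camera adjusted p = 0.0139, 0.176 with an estimated correlation), glycocalyx genes (3 rose and 13 fell of 23, median -0.79, moving to -0.49 with library size scaling, camera adjusted p = 0.03, 0.233 with an estimated correlation) and flow mechanosensors (5 rose and 16 fell of 32, 6 and 18 adjusted over the list alone, median -0.29, moving to 0.00 with library size scaling, camera adjusted p = 0.0207, 0.418 with an estimated correlation). Camera called 23 of 37 lists, and with an estimated correlation 3. The glycocalyx list lost its call without static A-485 replicate 3 or with the stricter filter (adjusted p = 0.0502 to 0.0895).

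Among single genes, the growth-response gene EGR1 rose (log2 fold change 4.85 ± 0.75), with 1559 to 23806 reads in the A-485 libraries, and so did the sulfotransferase SULT1A1 (3.95 ± 0.20) and the transporter SLC16A4 (3.38 ± 0.18). The chemokine receptor CXCR4 (log2 fold change -9.11 ± 0.44) and the hyaluronan receptor LYVE1 (log2 fold change -8.81 ± 0.62) fell. GJA4 was 3994-fold lower (counting interval 716 to 157790) and IL33 was 1803-fold lower (499 to 14898). Of 14210 genes, 3990 rose and 4594 fell, 942 and 1793 of them at least 2-fold, and 99.3% of calls had the same sign in all 3 batches. Library size scaling gave 70.1% of calls higher, against 46.5%, and moved the median of all genes to 0.27.

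A-485 was compared with vehicle under flow to give the response to the inhibitor during shear stress. Most endothelial identity, DNA replication, mitosis, cholesterol synthesis and ribosomal protein genes were lower with A-485 here too. All 6 aryl hydrocarbon receptor targets fell, and 14 of 28 immediate early genes rose. Camera called these lists, and none kept its call with an estimated correlation (adjusted p = 0.075 to 0.628). The median of ribosomal protein genes, -0.70, was -0.30 after a trend in GC content, transcript length and expression was removed. KLF2 rose from 161 ± 14.7 to 471 ± 17.9 CPM (SD, n = 3 per group; log2 fold change 1.54 ± 0.22, adjusted p = 5.11e-05 in edgeR, same sign in 3 of 3 batches) and KLF4 did not pass (log2 fold change 0.14 ± 0.17, adjusted p = 0.506). NOS3 fell (log2 fold change -1.57 ± 0.14, adjusted p = 1.01e-06, 3 of 3), THBD rose (log2 fold change 1.94 ± 0.34, adjusted p = 0.000275, 3 of 3), ANGPT2 rose (log2 fold change 1.20 ± 0.32, adjusted p = 0.00508, 3 of 3) and EDN1 fell (log2 fold change -4.00 ± 0.29, adjusted p = 1.35e-07, 3 of 3). EP300 (log2 fold change 0.62 ± 0.13, adjusted p = 0.00108, 3 of 3) and CREBBP (log2 fold change 0.37 ± 0.12, adjusted p = 0.0153, 2 of 3) rose. CYP1B1 fell (log2 fold change -3.75 ± 0.59, adjusted p = 0.000107, 3 of 3), and VCAM1 did not pass (adjusted p = 0.68). CREBBP lost its call without flow A-485 replicate 2, flow A-485 replicate 3 or flow vehicle replicate 2 or with the transcript length offset (adjusted p = 0.0521 to 0.0655).

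Of 34 tested endothelial identity genes, 1 rose, 31 fell and 2 did not pass. Their median was -1.96 in log2 (camera adjusted p = 5.32e-11, 0.075 with an estimated correlation). PECAM1 (log2 fold change -3.54 ± 0.16) and the sialomucin EMCN (-5.52 ± 0.29) fell. Among 21 tested Notch and arterial genes, 1 rose, 18 fell and 2 did not pass. Their median was -2.13 in log2, or -2.03 with genes at the floor held there (camera adjusted p = 3.23e-05, 0.075 with an estimated correlation). Of 8 tested venous genes, 0 rose, 8 fell and 0 did not pass. Their median was -3.90 in log2, or -2.56 with genes at the floor held there, moving to -2.37 with the stricter filter (camera adjusted p = 2.98e-05, 0.075 with an estimated correlation). Among 13 tested BMP-SMAD targets, 0 rose, 8 fell and 5 did not pass. Their median was -1.08 in log2 (camera adjusted p = 0.0101, 0.075 with an estimated correlation). Of 20 tested vasoactive mediators, 1 rose, 14 fell and 5 did not pass. Their median was -1.87 in log2 (camera adjusted p = 0.000243, 0.075 with an estimated correlation). PTGS1, which makes prostanoids, fell (log2 fold change -2.88 ± 0.21). Among 22 tested shear-induced genes, 6 rose, 14 fell and 2 did not pass. Their median was -1.83 in log2 (camera adjusted p = 0.0238, 0.402 with an estimated correlation). The angiopoietin receptor TEK fell (log2 fold change -2.04 ± 0.13). Of 20 tested shear-repressed genes, 3 rose, 14 fell and 3 did not pass. Their median was -1.70 in log2 (camera adjusted p = 0.000709, 0.114 with an estimated correlation). THBS1, an inhibitor of angiogenesis, fell (log2 fold change -5.06 ± 0.19). Among 6 tested aryl hydrocarbon receptor targets, 0 rose, 6 fell and 0 did not pass. Their median was -2.43 in log2 (camera adjusted p = 0.00368, 0.075 with an estimated correlation). CYP1A1, a xenobiotic oxidase, was 2214-fold lower (counting interval 757 to 10741), and TIPARP fell (log2 fold change -0.64 ± 0.07).

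Of 30 tested genes of mitosis, 0 rose, 30 fell and 0 did not pass. Their median was -3.92 in log2 (camera adjusted p = 1.03e-11, 0.367 with an estimated correlation). CDK1 (log2 fold change -4.09 ± 0.20) and TTK (-4.97 ± 0.32) fell. Among 30 tested genes of DNA replication, 0 rose, 30 fell and 0 did not pass. Their median was -3.08 in log2 (camera adjusted p = 2.37e-15, 0.075 with an estimated correlation). MCM5 fell (log2 fold change -3.14 ± 0.10). Of 26 tested cholesterol synthesis genes, 2 rose, 22 fell and 2 did not pass. Their median was -0.95 in log2 (camera adjusted p = 6.5e-07, 0.0836 with an estimated correlation). SQLE, a monooxygenase of the pathway, fell (log2 fold change -1.56 ± 0.07). Among 30 tested ribosomal protein genes, 0 rose, 30 fell and 0 did not pass. Their median was -0.70 in log2 (camera adjusted p = 3.94e-08, 0.442 with an estimated correlation). Of 26 tested MYC and ribosome biogenesis genes, 2 rose, 14 fell and 10 did not pass. Their median was -0.48 in log2, moving to -0.26 with library size scaling (camera adjusted p = 0.0337, 0.709 with an estimated correlation). Among 28 tested immediate early genes, 14 rose, 3 fell and 11 did not pass. Their median was 0.74 in log2 (camera adjusted p = 0.0428, 0.628 with an estimated correlation). EGR1 rose (log2 fold change 6.89 ± 0.86). Of 23 tested NF-kB genes, 10 rose, 5 fell and 8 did not pass. Their median was 0.45 in log2 (the mean, -0.03, had the other sign) (camera adjusted p = 0.421). ICAM1 rose (log2 fold change 2.54 ± 0.30) and the cytokine IL6 fell (log2 fold change -4.78 ± 0.46). Among 31 tested interferon-stimulated genes, 12 rose, 7 fell and 12 did not pass. Their median was 0.47 in log2, or 0.41 with genes at the floor held there (camera adjusted p = 0.19). The MYC and ribosome biogenesis list lost its call without flow vehicle replicate 1 (adjusted p = 0.0662). The immediate early genes list lost its call without flow A-485 replicate 1, flow A-485 replicate 2, flow vehicle replicate 1 or flow vehicle replicate 2 or with the stricter filter or with library size scaling (adjusted p = 0.0507 to 0.16).

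Lower shifts with a camera call were also seen in matrix genes (4 rose and 24 fell of 34, 5 and 24 adjusted over the list alone, median -1.44, camera adjusted p = 2.94e-05, 0.114 with an estimated correlation), TGF-beta genes (3 rose and 12 fell of 24, median -1.08, camera adjusted p = 0.00606, 0.179 with an estimated correlation) and lymphatic markers (0 rose and 7 fell of 7, median -1.62, camera adjusted p = 0.00227, 0.075 with an estimated correlation). Camera also passed for YAP/TAZ targets (3 rose and 12 fell of 21, median -0.57, moving to -0.35 with library size scaling, camera adjusted p = 0.0428, 0.382 with an estimated correlation), stress response genes (6 rose and 16 fell of 24, median -0.77, camera adjusted p = 0.0189, 0.402 with an estimated correlation) and fibroblast markers (0 rose and 6 fell of 9, median -1.44, moving to -2.23 with only the compared groups fitted, camera adjusted p = 0.0189, 0.128 with an estimated correlation). It called 20 of 37 lists, and 0 with an estimated correlation. The YAP/TAZ targets list lost its call without flow A-485 replicate 1, flow A-485 replicate 2, flow vehicle replicate 1 or flow vehicle replicate 3 (adjusted p = 0.0509 to 0.0596).

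Among single genes, EGR1, IL11 (log2 fold change 5.45 ± 0.69) and FOS, a partner of JUN (log2 fold change 5.29 ± 0.85), rose. KIT was at least 164-fold lower and MYCN, a MYC relative, at least 97.4-fold lower, since neither had a read under flow with A-485. The chloride channel ANO2 was 1051-fold lower (counting interval 290 to 8684), LYVE1 was 469-fold lower (160 to 2277) and PI16 was 468-fold lower (200 to 1442). The mitotic gene SKA1 fell (log2 fold change -8.22 ± 0.84). CORO7, an actin regulator, was at least 291-fold higher, but it had 0, 540 and 874 reads in the static A-485 libraries. Of 14210 genes, 4536 rose and 4603 fell, 1179 and 2104 of them at least 2-fold, and 98.7% of calls had the same sign in all 3 batches. Library size scaling gave 65.3% of calls higher, against 49.6%, and moved the median of all genes to 0.22.

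**Figure D2:**
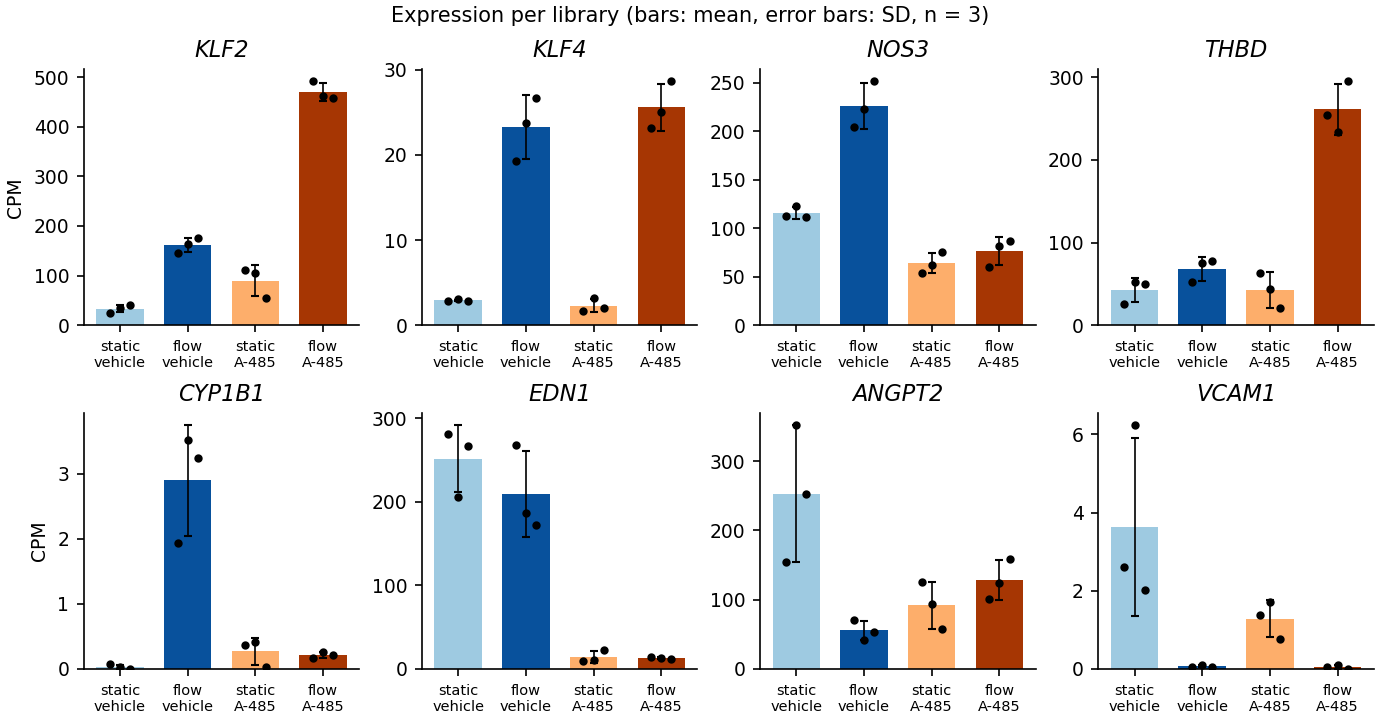
CPM of 8 genes named in advance, on linear axes from 0, with each library as a point, each group's mean as a bar and the SD as an error bar (n = 3). KLF2 is higher under flow than in static culture with vehicle and with A-485, and EDN1 is lower with A-485 in static culture and under flow.

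The interaction asked which flow responses differed with A-485, and a positive value means a change with flow that was higher with the inhibitor than with vehicle. The flow responses of KLF2 (log2 interaction 0.11 ± 0.31, adjusted p = 0.856 in edgeR) and KLF4 (log2 interaction 0.48 ± 0.27, adjusted p = 0.264) were not shown to differ. Responses of NOS3 and of aryl hydrocarbon receptor targets were lower with A-485. Of the mitosis genes 29 of 30 fell with flow and A-485, and camera called the difference from flow with vehicle (adjusted p = 0.456 with an estimated correlation). ANGPT2 fell with flow and vehicle but did not pass with A-485, and this difference passed. The interaction of ANGPT2 was positive (log2 interaction 2.66 ± 0.45, adjusted p = 0.00237, same sign in 3 of 3 batches), as was that of THBD (log2 interaction 1.95 ± 0.48, adjusted p = 0.0158, 3 of 3). That of NOS3 was negative (log2 interaction -0.72 ± 0.20, adjusted p = 0.0298, 3 of 3). CYP1B1 passed with an adjusted p = 0.00187 and lower response with A-485, with no fold given because static vehicle libraries were at the floor. EP300 (log2 interaction 0.02 ± 0.19), CREBBP (-0.24 ± 0.17), EDN1 (0.13 ± 0.38) and VCAM1 (adjusted p = 0.664) did not pass. NOS3 lost its call without flow vehicle replicate 2, flow vehicle replicate 3, static vehicle replicate 1 or static vehicle replicate 3 (adjusted p = 0.0513 to 0.0756). KLF4 gained a call without static A-485 replicate 2 (adjusted p = 0.0379).

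Of 30 tested genes of mitosis, 0 had a positive interaction, 24 a negative one and 6 did not pass (adjusted over the list alone, 0 positive and 29 negative). Their median was -1.87 in log2 (camera adjusted p = 5.02e-14, 0.456 with an estimated correlation). TTK (log2 interaction -2.59 ± 0.40), CDK1 (-1.63 ± 0.25) and the kinase AURKB (-2.20 ± 0.43) were among them. Among 30 tested genes of DNA replication, 0 had a positive interaction, 20 a negative one and 10 did not pass (adjusted over the list alone, 0 positive and 27 negative). Their median was -0.73 in log2 (camera adjusted p = 4.14e-13, 0.194 with an estimated correlation). CDT1 had a negative interaction (log2 interaction -2.27 ± 0.24). Of 6 tested aryl hydrocarbon receptor targets, 0 had a positive interaction, 4 a negative one and 2 did not pass (adjusted over the list alone, 0 positive and 5 negative). Their median was -2.05 in log2, or -2.03 with genes at the floor held there, moving to -3.14 without flow A-485 replicate 1 (camera adjusted p = 7.39e-07, 0.0312 with an estimated correlation). TIPARP (log2 interaction -1.34 ± 0.10), AHRR (-1.37 ± 0.15) and ALDH3A1 (-5.05 ± 0.59) were lower. Among 31 tested interferon-stimulated genes, 2 had a positive interaction, 10 a negative one and 19 did not pass (adjusted over the list alone, 3 positive and 12 negative). Their median was -0.34 in log2, moving to -0.52 to -0.18 without flow vehicle replicate 1 or flow vehicle replicate 2 (camera adjusted p = 0.000594, 0.456 with an estimated correlation). OAS1, an antiviral enzyme, was lower (log2 interaction -3.25 ± 0.34). Of 8 tested venous genes, 0 had a positive interaction, 2 a negative one and 6 did not pass (adjusted over the list alone, 0 positive and 3 negative). Their median was -0.68 in log2, moving to -1.10 without flow A-485 replicate 2 (camera adjusted p = 0.0123, 0.229 with an estimated correlation). NR2F2 was lower (log2 interaction -0.77 ± 0.19). Among 34 tested matrix genes, 2 had a positive interaction, 10 a negative one and 22 did not pass (adjusted over the list alone, 6 positive and 12 negative). Their median was -0.35 in log2 (camera adjusted p = 0.0121, 0.456 with an estimated correlation). The protease MMP2 was lower (log2 interaction -0.89 ± 0.10), as was the elastic fibre gene FBLN5 (log2 interaction -2.78 ± 0.33). Of 9 tested fibroblast markers, 0 had a positive interaction, 2 a negative one and 7 did not pass (adjusted over the list alone, 0 positive and 5 negative). Their median was -1.59 in log2 (camera adjusted p = 8.64e-05, 0.0665 with an estimated correlation). Among 30 tested ribosomal protein genes, 0 had a positive interaction, 0 a negative one and 30 did not pass. Their median was -0.11 in log2, moving to -0.18 with library size scaling and -0.21 to 0.00 without flow A-485 replicate 1, flow vehicle replicate 1, flow vehicle replicate 2 or static A-485 replicate 2 (camera adjusted p = 0.031, 0.726 with an estimated correlation). The ribosomal proteins list lost its call without flow A-485 replicate 2, flow A-485 replicate 3, flow vehicle replicate 2, static A-485 replicate 1, static A-485 replicate 3 or static vehicle replicate 1 or with the transcript length offset (adjusted p = 0.0558 to 0.442).

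Of 21 tested Notch and arterial genes, 9 had a positive interaction, 1 a negative one and 11 did not pass (adjusted over the list alone, 9 positive and 2 negative). Their median was 0.82 in log2, moving to 1.44 without flow vehicle replicate 3 (camera adjusted p = 0.00983, 0.412 with an estimated correlation). SEMA3G (2.93 ± 0.26) and EFNB2 (2.15 ± 0.22) had positive log2 interactions. Among 28 tested immediate early genes, 11 had a positive interaction, 0 a negative one and 17 did not pass (adjusted over the list alone, 13 positive and 0 negative). Their median was 0.76 in log2, or 0.73 with genes at the floor held there (camera adjusted p = 0.000405, 0.539 with an estimated correlation). JUN had a positive one (log2 interaction 2.16 ± 0.23). Of 23 tested NF-kB genes, 3 had a positive interaction, 1 a negative one and 19 did not pass. Their median was 0.68 in log2, or 0.59 with genes at the floor held there, moving to 0.32 to 1.21 without static A-485 replicate 2 or static vehicle replicate 2 (camera adjusted p = 0.0325, 0.674 with an estimated correlation). CCL2 (2.91 ± 0.49) and RELB (1.48 ± 0.23) had positive log2 interactions. Among 20 tested shear-repressed genes, 6 had a positive interaction, 1 a negative one and 13 did not pass (adjusted over the list alone, 7 positive and 1 negative). Their median was 0.54 in log2 (camera adjusted p = 0.0192, 0.456 with an estimated correlation). BMP4 had a positive one (log2 interaction 1.05 ± 0.14). Of 26 tested MYC and ribosome biogenesis genes, 3 had a positive interaction, 0 a negative one and 23 did not pass. Their median was 0.32 in log2, moving to 0.18 without static A-485 replicate 3 (camera adjusted p = 0.00983, 0.674 with an estimated correlation). Among 23 tested SRF and actin genes, 7 had a positive interaction, 0 a negative one and 16 did not pass (adjusted over the list alone, 9 positive and 1 negative). Their median was 0.26 in log2 (camera adjusted p = 0.0325, 0.674 with an estimated correlation). Of 22 tested shear-induced genes, 3 had a positive interaction, 5 a negative one and 14 did not pass (adjusted over the list alone, 4 positive and 6 negative). Their median was -0.03 in log2, or -0.28 with genes at the floor held there (camera adjusted p = 0.206). Camera called 14 of 37 lists, and with an estimated correlation 1. The NF-kB inflammatory and adhesion genes list lost its call without static A-485 replicate 3 or static vehicle replicate 2 (adjusted p = 0.0588 to 0.147). The MYC and ribosome biogenesis list lost its call without static A-485 replicate 3 or static vehicle replicate 1 (adjusted p = 0.0667 to 0.0755). The SRF and actin cytoskeleton genes list lost its call without flow A-485 replicate 3, flow vehicle replicate 2, flow vehicle replicate 3, static A-485 replicate 2, static A-485 replicate 3 or static vehicle replicate 1 (adjusted p = 0.0555 to 0.185).

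Among single genes, the interaction was positive for STC1 (log2 interaction 5.45 ± 1.27), UNC5B (log2 interaction 4.98 ± 0.42), CXCL8 (log2 interaction 4.81 ± 0.98), CXCR4 (log2 interaction 4.12 ± 0.70) and the transporter SLC45A4 (log2 interaction 3.75 ± 0.27). It was negative for SKA1 (log2 interaction -5.21 ± 1.10), the prostaglandin transporter SLCO2A1 (log2 interaction -3.80 ± 0.26), EMCN (log2 interaction -3.44 ± 0.35) and the BMP-responsive factor ATOH8 (log2 interaction -3.82 ± 0.65). The interaction was positive for 1145 genes and negative for 1066, with 288 and 512 beyond 2-fold, and 99.9% of these had the same sign in all 3 batches. Library size scaling gave 38.5% of calls positive, against 51.8%, and moved the median to -0.05.

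**Figure D3:**
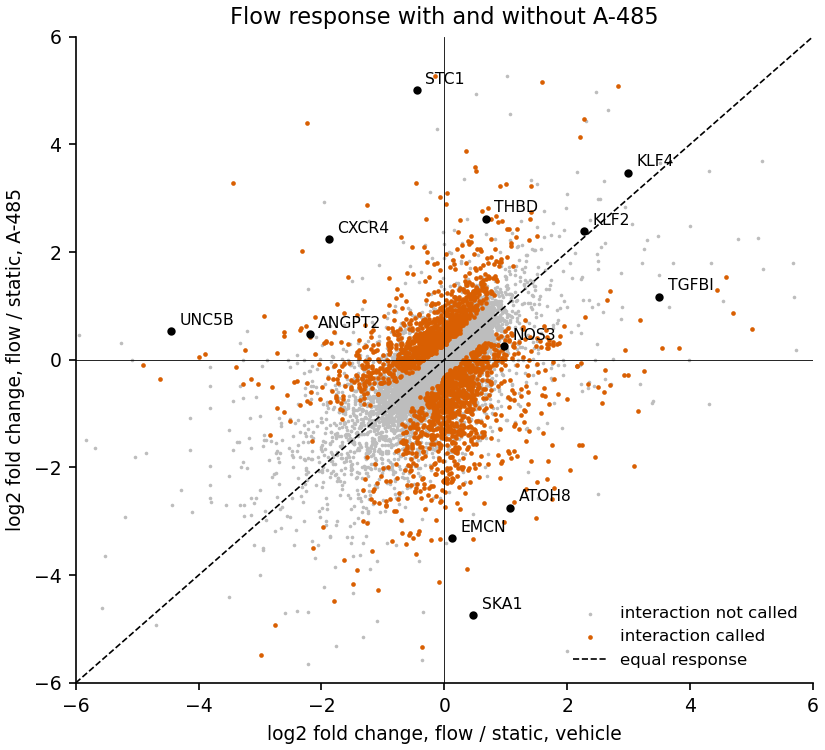
Each point is a gene, with the log2 fold change of flow over static culture with vehicle on the horizontal axis and with A-485 on the vertical axis. The axes end at 6 in log2, with 47 genes outside, genes left out of naming are not drawn, and the Spearman correlation across genes was 0.599.

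The flow responses with and without A-485 share no libraries, so their overlap was compared with independent lists. Both were higher for 2237 genes (864 for independent lists) and lower for 1790 (751), and 239 were called in opposite directions (1611). Spearman's rho was 0.599 across genes, which are not independent replicates. The A-485 responses in static culture and under flow were both higher for 3233 genes (1274) and lower for 3607 (1488), with rho 0.810. Of 3087 genes raised by flow with vehicle, 555 also passed in the interaction, 369 of them with a smaller or opposite response with A-485. Of 2951 lowered genes, 614 passed, 497 with a smaller or opposite response. Since genes picked by their own fold change regress, flow genes were chosen in 2 batches and measured in the third. The genes chosen as higher had a mean of batch medians of 0.51 ± 0.06 in log2 with vehicle and 0.48 ± 0.05 with A-485 (SD, n = 3 batches). The difference was -0.03 ± 0.10 (exact sign-flip test, two-sided p = 1). For genes chosen as lower, the values were -0.65 ± 0.10 and -0.49 ± 0.07, and the difference of 0.16 ± 0.14 gave an exact p = 0.25, which is the smallest this test can give with 3 batches. When a change of at least 2-fold was also required, the means were 1.44 with vehicle and 0.60 with A-485 for higher genes, and -1.35 and -0.90 for lower genes.

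**Figure D4:**
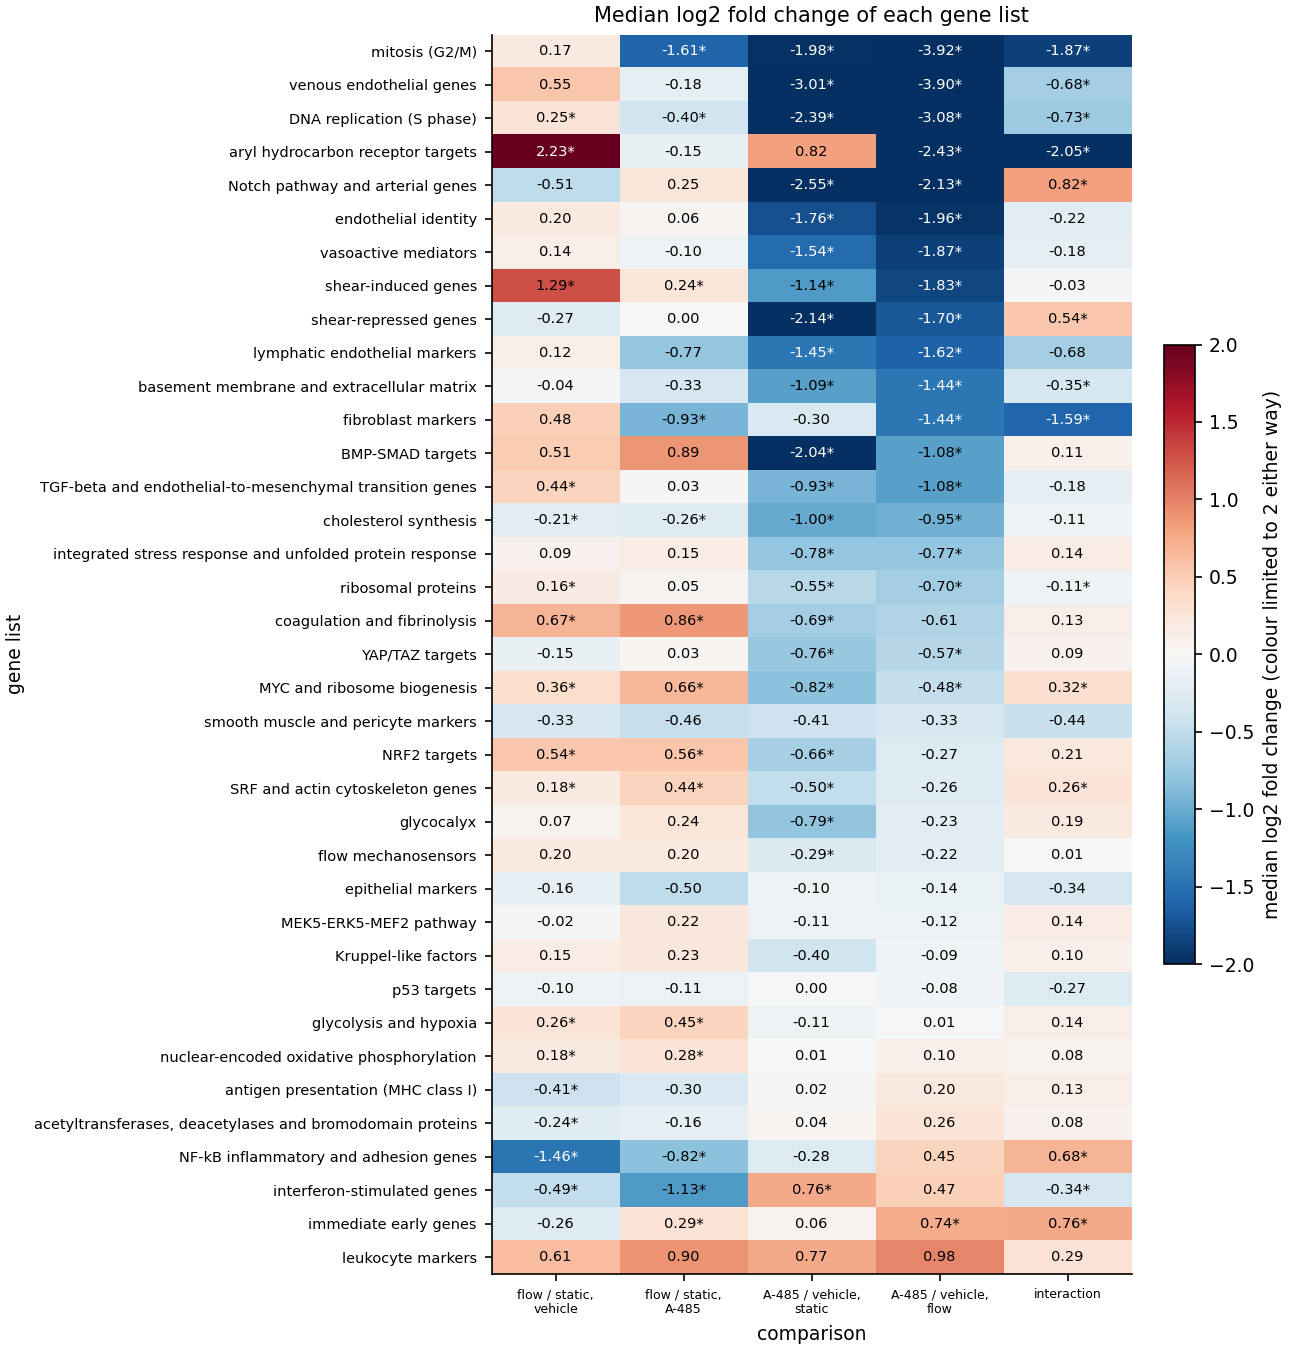
Median log2 fold change of each gene list (horizontal lines of cells) in each comparison (columns), with colour limited to 2 either way and a star where camera's adjusted p passed. Mitosis genes are -1.61 with flow and A-485, 0.17 with flow and vehicle, and -1.87 in the interaction.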

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

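Tests of scaling, of fibroblasts and of regrouped residuals, named here, were chosen after the results were seen. The results below had a difference between the flow responses with A-485 and with vehicle in the interaction test. It was positive for 1145 genes and negative for 1066. Genes with a positive value were STC1 (log2 interaction 5.45), UNC5B (4.98), CXCL8 (4.81), CXCR4 (4.12), CLK2 (4.05), SLC45A4 (3.75), ANGPT2 (2.66) and THBD (1.95). Genes with a negative value were SKA1 (-5.21), ATOH8 (-3.82), SLCO2A1 (-3.80), EMCN (-3.44), ITGA11 (-3.28), EXOC3L1 (-3.20), NEURL1B (-3.15) and NOS3 (-0.72). IL33 (adjusted p = 0.019), INHBB (0.0123), KIT (0.0161) and CYP1B1 (0.00187) passed in edgeR with a group at the floor and get no fold. CLK2 lost its call in DESeq2 (adjusted p = 0.205). ITGA11 lost its call with the transcript length offset (adjusted p = 0.0817). IL33 lost its call without flow A-485 replicate 3 (adjusted p = 0.947). INHBB lost its call without flow A-485 replicate 1 or flow A-485 replicate 2 (adjusted p = 0.0502 to 0.153). NOS3 lost its call without flow vehicle replicate 2, flow vehicle replicate 3, static vehicle replicate 1 or static vehicle replicate 3 (adjusted p = 0.0513 to 0.0756). CLK2 had 97, 0 and 0 reads in the flow vehicle libraries and 295 to 838 elsewhere.

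List medians with a camera call were 0.82 for Notch and arterial genes, 0.76 for immediate early genes, 0.68 for NF-kB genes, 0.54 for shear-repressed genes, 0.32 for MYC and ribosome biogenesis genes and 0.26 for SRF and actin genes. They were -2.05 for aryl hydrocarbon receptor targets, -1.87 for mitosis genes, -1.59 for fibroblast markers, -0.73 for DNA replication genes, -0.68 for venous genes, -0.35 for basement membrane genes, -0.34 for interferon-stimulated genes and -0.11 for ribosomal protein genes. With an estimated correlation only the aryl hydrocarbon receptor targets kept the call (adjusted p = 0.0312), and the others had adjusted p of 0.0665 to 0.726. The NF-kB inflammatory and adhesion genes list lost its call without static A-485 replicate 3 or static vehicle replicate 2 (adjusted p = 0.0588 to 0.147). The MYC and ribosome biogenesis list lost its call without static A-485 replicate 3 or static vehicle replicate 1 (adjusted p = 0.0667 to 0.0755). The SRF and actin cytoskeleton genes list lost its call without flow A-485 replicate 3, flow vehicle replicate 2, flow vehicle replicate 3, static A-485 replicate 2, static A-485 replicate 3 or static vehicle replicate 1 (adjusted p = 0.0555 to 0.185). The ribosomal proteins list lost its call without flow A-485 replicate 2, flow A-485 replicate 3, flow vehicle replicate 2, static A-485 replicate 1, static A-485 replicate 3 or static vehicle replicate 1 or with the transcript length offset (adjusted p = 0.0558 to 0.442).

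The first pattern weighed was the lower interaction of mitosis genes. Under TMM, median-of-ratios and library size scaling the weakest list median was -1.87, which argues against scaling as the cause. After a trend in GC content, length and expression was removed, the median was -1.93 (-1.94 with the replicate block). The lowest of 10000 random lists was -0.36, but random genes do not vary together as mitosis genes do. The weakest of 3 within-batch medians was -1.77, against a difference between batches. A candidate explanation is that the inhibitor slows division more under flow, which was not tested here and would need dividing cells to be counted in the 4 groups.

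The second was the fall of ribosomal protein genes with A-485. Library size scaling weakened the fall in static culture, from a median of -0.55 to -0.26, the weakest over 3 scalings and both flow states. The choice among these scalings was therefore not the whole cause. The trend in GC content, length and expression took the median from -0.55 to -0.0574 in static culture, inside the middle 95% of random lists (-0.15 to 0.37), and from -0.70 to -0.30 under flow, outside the middle 95% (-0.17 to 0.43) but above the lowest random list (-0.57). The trend explained 0.96% of the variance in static culture and 0.64% under flow. It was fitted on all genes outside the list, ribosomal protein genes not listed among them. It therefore cannot tell a trend among short, abundant transcripts from a fall shared by ribosomal protein genes, and the cause stays open in both flow states.

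The third was the lower interaction of fibroblast markers. If A-485 had changed only the share of fibroblasts, and not the markers' expression within cells, all markers would move alike. With A-485 under flow, 6 markers above 0.5 CPM in groups above the floor ranged over 4.83 in log2, from COL1A2 (-4.12 ± 0.25) to DCN (0.71 ± 0.35, SE). The abundant fibroblast gene COL1A1 was at 0.241 ± 0.0510 CPM under flow with vehicle, 0.104 ± 0.0558 under flow with A-485, 0.274 ± 0.102 in static vehicle and 0.362 ± 0.122 in static A-485 libraries (SD, n = 3). A shared mixture alone is unlikely for A-485 under flow, and was not tested for the interaction.

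Splits of the 6 libraries of each pair were too few (10) for a share under 0.05. The real split was the only 1 of 10 to call as many genes, for flow with vehicle (6038, highest other 0), for flow with A-485 (7592, highest other 0), for A-485 in static culture (8584, highest other 1) and for A-485 under flow (9139, highest other 0). Of the 4 splits in each that part all batches, the highest other called 0. For the interaction, 6 of 100 drawn regroupings of the A-485 labels (of 200) called as many genes as the real 2211, with 5651 the highest other, so by this test chance was not excluded. All 5 others kept the labels of the flow libraries and turned those of 4 of the 6 static libraries, so that most of the A-485 effect in static culture changed sign and was added. With 2 of the 6 static labels turned, the 4 drawn regroupings called 70 to 288 genes. A test that first removed the flow and A-485 effects was added after that result was seen. It found 1 of 100 regroupings of residuals (of 462) as large, the real one (2285 genes with limma, highest other 1). Its residuals were pooled over all groups, so it argues against chance without excluding it. Neither test kept libraries within their batches.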

How the results depend on the processing

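Library size scaling was the only test here chosen after the data were seen. Counts of genes stayed within 1.5 times their values under every alternative chosen before the data were examined, and those that did not under library size scaling were 2461 genes higher with flow and A-485, and 6758 higher and 2879 lower with A-485 in static culture. That scaling also changed the shared flow genes (1289 higher, 2745 lower) and the shared A-485 genes (5500 higher, 2352 lower). It makes no correction for composition. No call of a named gene or list changed direction. Of 185 list medians 15, all without a camera call, changed sign between the 3 scalings. The side with more calls could also turn, as for flow with A-485, with 3976 higher and 3616 lower under TMM and 3533 and 4008 under median-of-ratios scaling. When flow genes were chosen by a change of at least 2-fold, the held-out medians moved to 1.44 with vehicle and 0.60 with A-485 (difference -0.84) for higher genes, and to -1.35 and -0.90 (difference 0.45) for lower genes. With 1 library left out, called genes higher and lower ranged over 2397 to 3270 and 2318 to 3245 for flow with vehicle, 3116 to 4002 and 3323 to 3770 for flow with A-485, 3493 to 4334 and 4122 to 4636 for A-485 in static culture, 4196 to 4700 and 4265 to 4743 for A-485 under flow, and 790 to 1095 and 776 to 1167 for the interaction. The replicate block gave 1473 and 1249 genes in the interaction, and changed the calls of FAP, FCER1G (in 2 comparisons) and TAP2, which were lost, of ERAP2, TLL1, RRS1, SMTN and CYCS in the interaction, which were gained, and of 4 lists, and no other call of a named gene or list. Over all alternatives but an estimated correlation, 14629 values of named genes stayed on their side of the threshold, 290 lost and 90 gained a call, and for lists 3367 stayed, 69 lost and 36 gained. An estimated correlation ended 83 list calls, leaving 3 with A-485 in static culture and 1 in the interaction. DESeq2 was not run for lists. At this depth a 2-fold change was called in most simulated genes, and 33 genes had 0 reads in 1 library and at least 100 in another of the same group, of which 4 were called.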

Other observations

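No tests in this part were chosen after the results were seen, but the genes named were. Ribosomal protein genes took 4.60% of reads in static vehicle libraries, 4.71% under flow with vehicle, 3.80% in static culture with A-485 and 3.38% under flow with A-485. Within the acetyltransferase, deacetylase and bromodomain genes the deacetylase HDAC9 fell with A-485 in static culture (log2 fold change -3.02 ± 0.23) and under flow (log2 fold change -2.62 ± 0.23), while the acetyltransferase KAT6B rose (log2 fold change 0.87 ± 0.08 and 0.87 ± 0.08). CD68, listed as a leukocyte marker, rose with flow and with A-485 in all 4 pairs, by 1.03 ± 0.12, 1.92 ± 0.12, 1.16 ± 0.12 and 2.05 ± 0.12 in log2.

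Lists with no camera call in any comparison were as follows for flow with vehicle. They were p53 targets (5 rose and 4 fell of 24, median -0.10, the mean, 0.00, had the other sign, camera adjusted p = 0.965), Kruppel-like factors (4 rose and 2 fell of 14, median 0.15, camera adjusted p = 0.493), genes of the MEK5-ERK5-MEF2 pathway (4 rose and 3 fell of 9, median -0.02, the mean, 0.52, had the other sign, camera adjusted p = 0.401), smooth muscle and pericyte markers (1 rose and 2 fell of 9, median -0.33, camera adjusted p = 0.493), leukocyte markers (1 rose and 0 fell of 3, median 0.61, camera adjusted p = 0.28) and epithelial markers (0 rose and 2 fell of 6, median -0.16, camera adjusted p = 0.229). In the same order, medians over the 5 comparisons ran from -0.27 to 0.00, -0.40 to 0.23, -0.12 to 0.22, -0.46 to -0.33, 0.29 to 0.98 and -0.50 to -0.10, and with A-485 in static culture 4 Kruppel-like factors rose and 7 fell.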
